A study of Mus musculus with 102 samples.

How the data were processed

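Per the labels, tissue was flash frozen, total RNA was taken with TRI-Reagent and cleaned with a Monarch kit, and libraries were made from 1 µg with a TruSeq RNA kit and a ligation-mediated protocol. The submitters' processing notes name bcl2fastq 2.20, cutadapt, HISAT2 2.1.0, SAMtools, R 3.5.1 and DESeq2, on GRCm38. The read counter and the annotation are not stated there. The deposited signal values are read counts per gene symbol that the authors divided by 1 size factor per library. Every column is whole multiples of 1 step, so whole reads were recovered, to within 0.01 of a read, for 100% of values in the 3 tables. No Xist reads were found in any library and Ddx3y was read in all, as the male labels say. Mitochondrially encoded genes had no reads in any table.

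The main tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2 of the deposited value plus 1. Genes needed a value of 10 in at least 5 libraries of an ageing table or 3 of the mTOR table. One linear model per table held a mean for each age, or for each genotype and age, and each p came from a 2-sided moderated t-test, or a moderated F-test for any difference among the 6 ages. Benjamini-Hochberg adjustment ran over all tested genes of 1 contrast, and an adjusted p under 0.05 is called. Old animals of 21 and 23 months were pooled. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as further tools. limma stayed first because the unit is a normalized signal, and it calls 103, 60 and 1230 genes for brain at 26 months, spleen at 26 months and mTOR against WT, where edgeR calls 115, 707 and 1283 and DESeq2 169, 896 and 1897. Titles of the ageing samples carry ET codes that the labels do not explain, and these were not used. Contrasts, filters, tests, gene lists and the rule for naming genes were fixed before the data were examined.

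51 lists of cell-type and pathway genes were written from general knowledge, 34 were tested in each table, and each was tested with camera (limma), once with a preset correlation between genes of 0.01 and once with the correlation estimated. A list passes at adjusted p under 0.05 over the lists of the contrast. Counts within a list are given over all genes unless the words adjusted over the list alone are used. A list mean is the mean over its tested members of the log2 values of a library. After the first results an exact permutation test of list means was added, which goes through every division of the animals into groups of the same sizes, within age where genotypes are averaged, with a 2-sided p. Named genes are the 6 largest increases and 6 largest decreases among called genes with a mean of at least 50 in the higher group, leaving out predicted genes, immunoglobulin and T-cell receptor variable segments, pseudogenes and sex-linked genes, and for passing lists the members with the smallest p. The same rule at 20 months was added after the data were seen.

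The ageing signature in the mTOR table is the set of genes called higher or lower in spleen at 26 against 3 months, tested with camera in other animals. Overlaps used 2-sided Fisher tests over genes tested on both sides. The region around Mtor was tested by a 2-sided Fisher test of genes within 5 Mb against all others. Only genes with 1 position in GENCODE M21 entered it (99.7% of the tested genes). All pairs of libraries of a table were compared by the variance of genes with few reads over that expected from read sampling, and 2 brain pairs below 1 were averaged to 1 sample each. Brain therefore has 43 samples from 45 libraries. The plan had counted all 45 separately, and the averaging was decided after the data were examined.

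The main tests and the pair test were tested on simulated data with known changes. For brain at 26 months limma recovered 85.0% of 2-fold changes, against 34.3% for spleen at 26 months and 67.0% for mTOR against WT averaged over age. Of its calls 2.54 to 5.34% were false, while DESeq2 reached 16.0% in young mTOR against WT. The simulated genes varied independently of each other, so these shares need not hold for real genes that move together. Random divisions of the real spleens gave up to 1979 calls for 26 against 14 months. Independent draws of reads from 1 sample gave a variance ratio of 0.995, and a draw against part of its own reads 0.255. Groups were also divided at random 100 times, or in all 10 ways where the mTOR table allows no more, and the analysis repeated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.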

Results

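The series holds RNA sequencing of brain and spleen from 45 male C57BL/6J mice of 6 ages. It also holds spleen from 12 further male mice labelled WT or mTOR, whose titles carry BL6J as well. In the ageing animals each brain has a spleen from the same mouse, with 7 animals at 3 months, 9 at 5, 8 at 8, 9 at 14, 7 at 20 and 5 at 26. The mTOR table has 3 WT and 3 mTOR animals at 5 months (young), and 3 of each genotype at 21 or 23 months (old). The labels give the genotype by name only and do not describe the allele. Reads in genes ran from 4072076 to 13655235 per brain library, 3031246 to 11702988 per spleen library and 7733716 to 14112504 in the mTOR table. All expression values below are normalized read counts, given as mean ± SD with the number of animals n, and log2 fold changes carry their SE. In 2 pairs of brain libraries, replicates 1 and 6 at 5 months and replicates 4 and 7 at 8 months, the members differed by less than the sampling noise of separate reads, so they are not independent samples, and each pair was averaged and counted as 1 sample. The brain groups then hold 8 samples at 5 months and 7 at 8 months, 43 in all.

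In the brain, genes of complement and of reactive glia were higher at 26 than at 3 months. C4b, a complement component that tags surfaces for clearance, rose from 69.2 ± 15.7 (n = 7) at 3 months to 520 ± 178 (n = 5) at 26 months. At the ages between it stood at 82.0 ± 20.9 (n = 8) at 5, 112 ± 47.4 (n = 7) at 8, 136 ± 46.1 (n = 9) at 14 and 294 ± 64.7 (n = 7) at 20. Its log2 fold change at 26 months was 2.85 (SE 0.22, limma adjusted p = 3.20e-13). Lyz2, the lysozyme of macrophages and microglia, rose from 13.3 ± 7.06 to 52.3 ± 23.8, a log2 change of 1.92 (SE 0.32, limma adjusted p = 0.000264). The acute-phase protease inhibitor Serpina3n, made by reactive astrocytes, rose from 51.7 ± 11.3 at 3 months to 87.2 ± 25.1 at 20 and 210 ± 138 at 26 (log2 1.83, SE 0.24, limma adjusted p = 2.93e-06). A2m encodes a broad-range protease trap and rose by log2 1.65 (SE 0.29), from 17.5 ± 6.67 to 55.6 ± 12.7. Gpnmb marks lipid-laden and disease-associated microglia and rose by 1.45 (SE 0.18, limma adjusted p = 1.23e-06), from 28.0 ± 7.03 to 76.9 ± 11.6. Lag3, an inhibitory receptor that binds MHC class II, rose by 1.44 (SE 0.25), from 25.1 ± 7.23 to 68.1 ± 13.5. None of these 6 genes had a 3-month library inside the range of the 26-month group. C4b shares nearly all of its sequence with C4a, Lyz2 with Lyz1, and Serpina3n belongs to a family of close copies, so reads may be assigned between copies. C4b lies on chromosome 17 from 34728380 to 34743882, minus strand (GENCODE M21 on GRCm38, 1-based).

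Genes induced by neuronal activity were lower at 26 than at 3 months. The mean of the immediate early list was below its 3-month level from 5 months on, and 0 genes passed as lower at 26 against 14 months. Arc, which controls AMPA receptor uptake at active synapses, fell from 731 ± 194 (n = 7) to 319 ± 175 (n = 5), a log2 change of -1.29 (SE 0.28, limma adjusted p = 0.00947). Fos, a subunit of the AP-1 transcription factor, fell from 956 ± 226 to 478 ± 183 (log2 -1.05, SE 0.24, limma adjusted p = 0.0156). Ier2 fell from 110 ± 36.0 to 51.4 ± 18.3 (log2 -1.08, SE 0.26), and the AP-1 subunit Junb from 221 ± 64.8 to 119 ± 50.3 (log2 -0.94, SE 0.21). Btg2, an antiproliferative early response gene, fell from 296 ± 99.1 to 150 ± 26.2 with no overlap between the groups (log2 -0.93, SE 0.20, limma adjusted p = 0.00746). Arl4d, a small GTPase of the ARF family, fell from 149 ± 37.7 to 86.4 ± 26.5 (log2 -0.78, SE 0.18, limma adjusted p = 0.0151). When each 26-month library was left out in turn, 7 of the 12 named genes kept their call every time. The 3-month libraries were not left out in turn. Arc lost it without replicate 3 of the 26-month group, Ier2 without replicate 2, 3, 4 or 5, Fos without 5, Junb without 3 or 5, and Arl4d without 4 or 5. Of 15546 tested genes, 103 passed in limma (89 higher, 14 lower), 115 in edgeR and 169 in DESeq2, and 100 passed in all 3; limma gave 67 without replicate 1 of 26 months and 53 in a fit of the 2 groups alone.

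**Figure D1:**
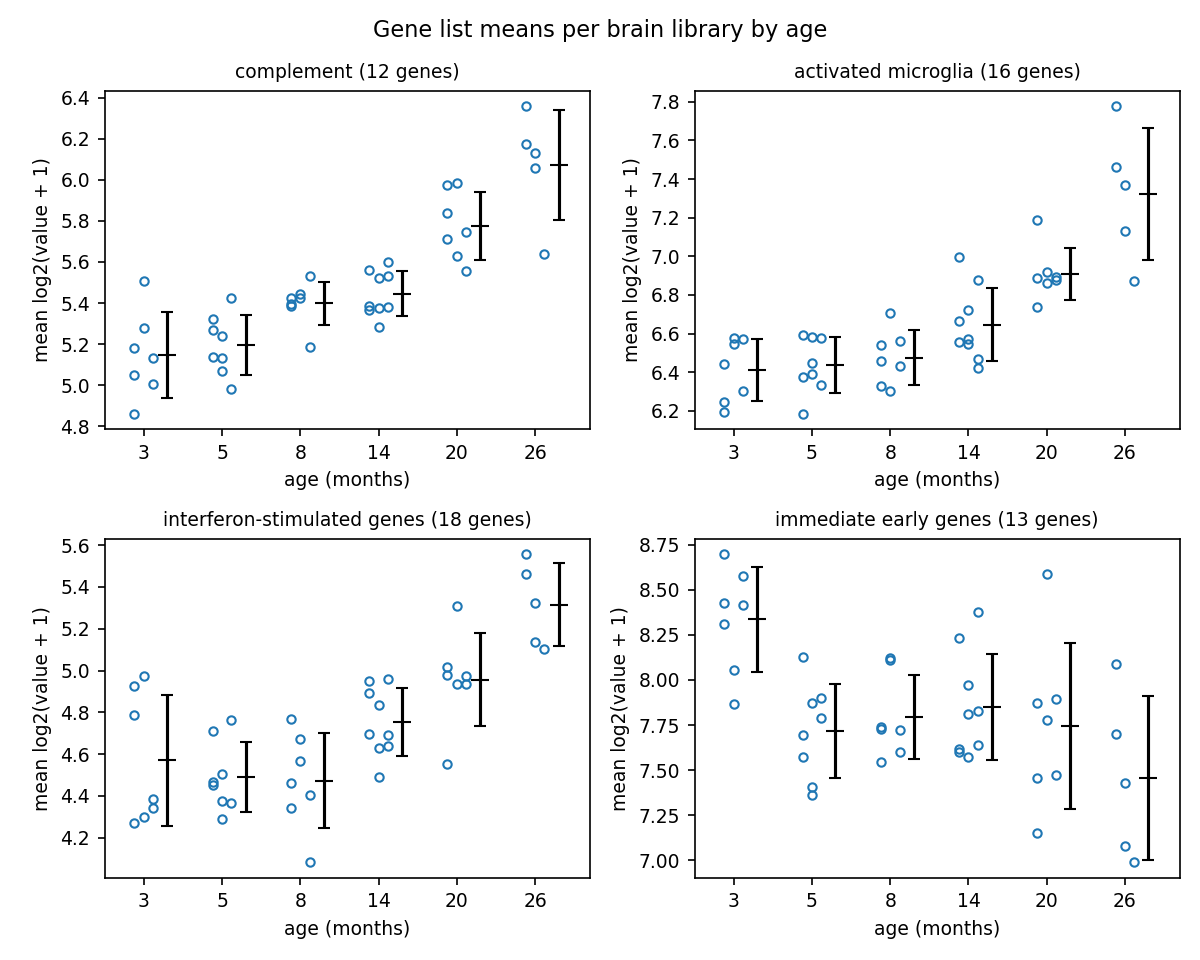
Mean log2 expression of the complement, activated microglia, interferon-stimulated and immediate early gene lists in each brain sample by age. Points are samples and bars show mean ± SD.

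Of 34 gene lists tested in brain at 26 against 3 months, 14 passed camera with the preset correlation, 7 higher and 7 lower, and 6 of them also held with an estimated correlation. By camera in limma, the complement list averaged 5.15 ± 0.21 (log2, n = 7) at 3 months and 6.07 ± 0.27 (n = 5) at 26 months (adjusted p = 7.42e-06 with an estimated correlation). Besides C4b it included C3ar1 (log2 1.34), the receptor for the C3a peptide, and C3 itself (5.62 ± 3.03 to 29.1 ± 16.8). For activated microglia the mean went from 6.41 ± 0.16 to 7.32 ± 0.34 (camera adjusted p = 9.39e-05 with an estimated correlation). Its pattern-recognition receptor Clec7a, at 2.53 ± 1.88 and 34.5 ± 22.1, changed by 3.36, and the integrin Itgax, at 1.41 ± 1.52 and 25.1 ± 11.9, by 3.60. MHC class I presentation went from 5.23 ± 0.28 to 6.15 ± 0.30 (camera adjusted p = 6.41e-05 with an estimated correlation), carried by H2-K1 (82.0 ± 15.2 to 163 ± 23.9), H2-D1 (161 ± 49.8 to 309 ± 66.8) and H2-Q4 (log2 1.47), whose sequences overlap in part. The reactive astrocyte list went from 4.77 ± 0.10 to 5.44 ± 0.31 (camera adjusted p = 0.000118 with an estimated correlation), with the intermediate filament Vim at 161 ± 31.7 and 270 ± 52.4, and the ferroxidase Cp 0.70 higher. Interferon-stimulated genes went from 4.57 ± 0.31 to 5.32 ± 0.20 (camera adjusted p = 0.000118 with an estimated correlation). In that list Oas1a, a sensor of double-stranded RNA, passed alone over all genes (log2 2.08) and 15 of 18 members were higher when adjusted over the list alone. Immediate early genes averaged 8.34 ± 0.29 at 3 months and 7.46 ± 0.45 at 26 months (camera adjusted p = 0.00289 with an estimated correlation). Of their 13 members 12 were lower when adjusted over the list alone. In the exact permutation of samples 8 lists passed, these 6 among them (adjusted p = 0.0107 to 0.0286).

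8 brain lists passed at the preset correlation and were lost under the estimate. Myelinating oligodendrocyte genes were higher by a mean of 0.28 (adjusted p = 0.0786 with an estimated correlation), with the lipid carrier Apod at 835 ± 151 and 1370 ± 373. Choroid plexus genes were higher by 0.37 (adjusted p = 0.377 with an estimated correlation). Lower by small amounts were nuclear-encoded respiratory chain (-0.20; 0.231 with the estimate), ribosomal protein (-0.18; 0.231), endoplasmic reticulum stress (-0.19; 0.144), pan-neuronal (-0.17; 0.0870), striatum (-0.25; 0.202) and cytosolic heat shock genes (-0.18; 0.137). The other 20 lists did not pass camera (limma): MHC class II presentation (adjusted p = 0.0511), GABAergic neuron (0.0715), homeostatic microglia (0.0922), glutamatergic synapse (0.0922), endothelial cell and pericyte (0.0926), oligodendrocyte precursor and newly formed oligodendrocyte (0.130), extracellular matrix and fibroblast (0.171), neurogenesis, cerebellum and cholesterol synthesis (each 0.325), T cell (0.367), p53 targets and senescence (0.477), astrocyte identity (0.502), lysosome and autophagy (0.616), hypothalamic and pituitary hormones (0.653), circadian clock, B cell and ATF4 targets (each 0.742), plasma cell (0.805) and erythroid (0.945). The mitochondrially encoded list had 0 tested members in any table.

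Immediate early genes stood below their 3-month level at the ages between as well. Their list mean was 7.72 ± 0.26 (n = 8) at 5 months, 7.80 ± 0.23 (n = 7) at 8, 7.85 ± 0.29 (n = 9) at 14 and 7.74 ± 0.46 (n = 7) at 20, each against 8.34 ± 0.29 at 3 months. Fos stood at 546 ± 140 at 5 months and 680 ± 219 at 14, and Arc at 426 ± 169 and 497 ± 210. The list passed camera with an estimated correlation at 5, 8, 14 and 20 months (limma adjusted p = 0.00591, 0.0467, 0.0346 and 0.0313), and at none of them the exact permutation of samples (adjusted p over the 34 lists = 0.0581, 0.139, 0.0832 and 0.0962). At 5 months 12 of 13 members passed when adjusted over the list alone. These comparisons share the 3-month animals, so their repeats at later ages are not independent. No single gene passed limma at 5, 8 or 14 months: 0 each. At unadjusted p under 0.05 there were 495, 558 and 661 genes; edgeR passed 0 each, and DESeq2 0, 0 and 3. At 14 months MHC class I and complement lists were higher (camera adjusted p = 0.00953 for each with an estimated correlation; permutation 0.0238 and 0.0461). The list tests at ages other than 26 months, and the permutation test, were chosen after the first results were seen.

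At 20 months 27 genes passed in brain by limma (25 higher, 2 lower), with 41 in edgeR and 82 in DESeq2. C4b was again the largest at log2 2.07 (limma adjusted p = 1.14e-09). Vwf, the adhesive glycoprotein of endothelium and platelets, rose from 54.3 ± 7.86 (n = 7) to 146 ± 54.0 (n = 7), log2 1.34 (SE 0.21, limma adjusted p = 0.000238), and stood at 121 ± 46.4 (n = 5) at 26 months. Acer2, an alkaline ceramidase, rose from 85.6 ± 14.7 to 172 ± 56.3 (log2 0.96, SE 0.16), and Etnppl, an astrocyte enzyme of phosphoethanolamine breakdown, from 339 ± 49.2 to 604 ± 156 (log2 0.80, SE 0.12, limma adjusted p = 0.000214). The secreted glycoprotein Lgals3bp rose from 51.3 ± 13.4 to 99.6 ± 21.8 and Gpnmb by 0.86. Nrep, a protein of neuronal growth, fell from 1524 ± 213 to 1026 ± 111 (log2 -0.57, SE 0.11), and Dio2, which activates thyroid hormone, from 620 ± 40.1 to 479 ± 47.1 (log2 -0.38, SE 0.08, limma adjusted p = 0.0315). Complement (camera adjusted p = 0.000269 with an estimated correlation; permutation adjusted p = 0.00991), MHC class I (0.00494; 0.0149), reactive astrocyte (0.00816; 0.0149) and activated microglia lists (0.0180; 0.00991) were higher by both tests. At 26 against 14 months 26 genes passed, all higher (7 to 23 when 1 library of 26 months was left out), and 75 genes passed the test of any age difference.

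In the spleen at 26 months, genes lower than at 3 months included Cr2 and Vpreb3 of B cells. Cr2, the complement receptor of follicular and marginal zone B cells, fell from 10142 ± 3239 (n = 7) to 4377 ± 3182 (n = 5), log2 -1.44 (SE 0.32, limma adjusted p = 0.0334). Vpreb3, a chaperone of immunoglobulin assembly in B cells, fell from 110 ± 23.2 to 39.3 ± 28.1 (log2 -1.75, SE 0.36, limma adjusted p = 0.0172), with 38.0 ± 14.6 (n = 7) at 20 months. The cyclic AMP sensor Rapgef4 fell from 276 ± 75.5 to 116 ± 65.6 (log2 -1.41, SE 0.28), and carboxypeptidase M (Cpm) from 303 ± 74.1 to 143 ± 80.4 (-1.28). The collagen Col19a1 fell from 55.9 ± 26.9 to 18.5 ± 12.7 (-1.73) and Emid1 from 121 ± 16.1 to 58.0 ± 34.2 (-1.23). Wipf3, an actin regulator of the WASP-interacting family, rose from 7.92 ± 6.55 to 62.2 ± 31.9 (log2 3.03, SE 0.54, limma adjusted p = 0.00834) and had reached 48.1 ± 18.9 (n = 9) at 14 months. Pkhd1l1, a large membrane protein related to fibrocystin, rose from 19.0 ± 6.80 to 251 ± 194 (log2 3.08, SE 0.58, limma adjusted p = 0.0110) with no overlap. Fn3k, which removes sugar adducts from proteins, rose from 4.05 ± 2.37 to 104 ± 95.6 (log2 3.56, SE 0.86), and the lipid carrier Sec14l2 from 6.21 ± 3.67 to 98.1 ± 90.9 (3.18). The carboxylesterase Ces2g rose from 14.0 ± 10.6 to 282 ± 282 (3.28) and the apolipoprotein L gene Apol11b from 83.6 ± 59.4 to 2080 ± 2079 (3.32, limma adjusted p = 0.0498). Of 16243 tested genes 60 passed in limma (33 higher, 27 lower), with 2639 at unadjusted p under 0.05, 707 in edgeR (624 higher, 83 lower) and 896 in DESeq2 (727 higher, 169 lower). Each of the 12 named genes lost its call without at least 1 of the 5 libraries at 26 months, all 12 without replicate 2, and all but Wipf3 without replicate 1 or replicate 5. The count moved to 16 without replicate 1, 0 without 2, 1789 without 3, 682 without 4 and 3 without 5. In a limma fit of the 2 groups alone it was 0. Replicate 3 had 4650017 reads and 3.04% of them in Malat1, against 0.579 to 3.18% over all spleen libraries and medians of 1.71% at 3 and 1.09% at 26 months.

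**Figure D2:**
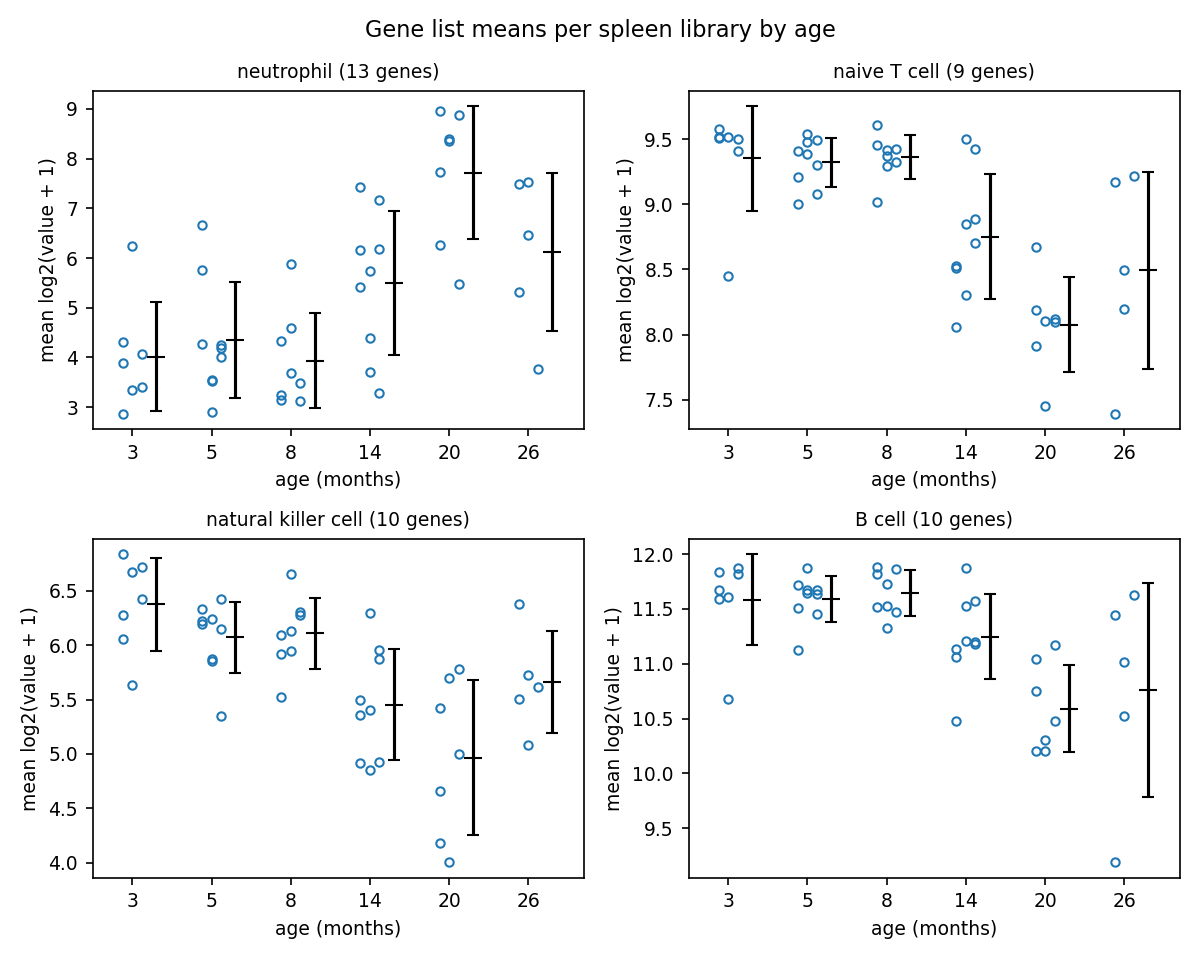
Mean log2 expression of the neutrophil, naive T-cell, natural killer and B-cell lists in each spleen by age. Points are libraries and bars show mean ± SD.

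Of 34 lists in spleen at 26 months, 21 passed camera with the preset correlation (14 higher, 7 lower), 0 passed with an estimated correlation and 0 passed the exact permutation of animals. Cell cycle genes had the smallest preset value and rose by a mean of 1.23 (limma camera adjusted p = 0.221 with an estimated correlation). Of these 27 of 28 were higher when adjusted over the list alone, and the proliferation marker Mki67 stood at 1932 ± 620 (n = 7) and 12684 ± 11489 (n = 5). Megakaryocyte genes were 1.84 higher (0.221 with the estimate), with the platelet integrin Itga2b at 140 ± 26.7 and 974 ± 1428. Erythroid genes were 2.25 higher (0.237), neutrophil genes 2.097 higher (0.237), B-cell genes 0.82 lower (0.237), naive T-cell genes 0.86 lower (0.221), T-cell genes 0.45 lower (0.281) and natural killer genes 0.71 lower (0.311). Effector and exhausted T-cell genes were 0.48 higher (0.237), with the granzyme Gzmk at 9.26 ± 7.11 and 45.9 ± 26.7 (log2 2.34) and the chemokine Ccl5 at 231 ± 54.1 and 448 ± 100 (log2 0.95). Red pulp macrophage genes were 0.74 higher (0.281), with Adgre1, which encodes F4/80, at 454 ± 177 and 1056 ± 517. ATF4 targets were 0.48 higher (0.237), with asparagine synthetase (Asns) at 31.5 ± 33.4 and 232 ± 201. The remaining lists that passed only at the preset value were inflammatory cytokines (0.221 with the estimate), dendritic cell, p53 targets, cholesterol synthesis and lysosome (each 0.237), respiratory chain, glycolysis and hypoxia, and MHC class II (each 0.281), endoplasmic reticulum stress (0.311) and interferon-stimulated genes (0.435). The other 13 did not pass camera (limma): extracellular matrix (adjusted p = 0.0674), cytosolic heat shock (0.0765), adipocyte (0.0779), immediate early (0.202), splenic stroma (0.303), regulatory and follicular helper T cell (0.515), circadian clock (0.560), ribosomal proteins (0.641), plasma cell (0.747), exocrine pancreas (0.853), germinal centre (0.885), mTOR pathway components (0.896) and MHC class I (0.998).

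With all libraries, more spleen genes were called against 3 months at 20 months than at any other age, an order that turned without the libraries under 5000000 reads. Genes of granule-forming neutrophil precursors were the largest: the iron-binding Ltf stood at 35.9 ± 71.3 (n = 7) at 3 months and 828 ± 545 (n = 7) at 20 months (log2 5.53, SE 0.86, limma adjusted p = 0.000110), and at 253 ± 216 (n = 5) at 26. Ngp went from 54.2 ± 104 to 1236 ± 891 (5.43) and the cathelicidin Camp from 19.5 ± 30.5 to 434.4 ± 278.1 (5.11). The ficolin Fcnb went from 2.51 ± 5.44 to 78.6 ± 62.6 (4.90) and cathepsin G (Ctsg) from 2.03 ± 4.15 to 65.3 ± 42.9 (4.62). Myeloperoxidase (Mpo) went from 4.96 ± 6.84 to 165 ± 100 with no overlap (5.12, SE 0.94, limma adjusted p = 0.000432). Lef1, a transcription factor of naive T cells, fell from 1633 ± 885 to 319 ± 99.1 (log2 -2.10, limma adjusted p = 0.00164), and Dapl1 from 124 ± 46.7 to 26.7 ± 27.6 (-2.68). The natural killer receptor Ncr1 fell from 74.5 ± 27.1 to 20.3 ± 14.0 with no overlap (-2.33), Klra4 from 82.7 ± 37.3 to 12.8 ± 11.1 (-2.84) and Klra8 from 69.0 ± 29.5 to 15.2 ± 13.3 (-2.59); reads of the Klra family may be exchanged between its members. Lypd6b fell from 71.2 ± 26.9 to 17.5 ± 14.0 (-2.40). In all 1733 genes passed limma (973 higher, 760 lower), 1984 passed edgeR and 2476 DESeq2. Without the fifth 3-month spleen, whose Cr2 of 3274 lay below the 10088 to 12977 of the others, 2739 genes passed at 20 months and 685 at 26, and without libraries under 5000000 reads 685 and 1481; in the fit without replicate 3 of 26 months they were 1929 and 1789. The neutrophil list stood at 4.02 ± 1.09 at 3 months, 5.50 ± 1.45 (n = 9) at 14, 7.72 ± 1.34 at 20 and 6.12 ± 1.59 at 26, and naive T-cell genes at 9.35 ± 0.40, 8.75 ± 0.48, 8.08 ± 0.36 and 8.49 ± 0.75. Exocrine pancreas genes stood at 1.88 ± 1.42 at 3 months and 3.60 ± 2.46 at 20 (limma camera adjusted p = 0.513 with an estimated correlation).

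At 20 months no spleen list held with an estimated correlation, and 11 passed the exact permutation of animals, chosen after the data were seen. Neutrophil genes were 3.70 higher (adjusted permutation p = 0.0132; camera adjusted p = 0.0758 with an estimated correlation) and megakaryocyte genes 1.53 higher (0.0132; 0.305). Naive T-cell genes were 1.27 lower (0.0132; 0.0572), natural killer genes 1.41 lower (0.0132; 0.0572), T-cell genes 0.96 lower (0.0132; 0.0765) and B-cell genes 0.99 lower (0.0132; 0.131). MHC class II (-0.70; 0.0170; 0.168), MHC class I (-0.41; 0.0396; 0.207) and cholesterol synthesis (-0.31; 0.0436; 0.239) were lower. p53 targets were 0.71 higher (0.0436; 0.239), where the cyclin-dependent kinase inhibitor Cdkn1a changed by 1.36. Cdkn1a was picked outside the naming rule. Circadian clock genes were 0.29 higher by permutation (0.0486) and did not pass camera (adjusted p = 0.236). At 14 months 52 genes passed limma, 51 of them higher, with 35 in edgeR and 231 in DESeq2; limma gave 13 without libraries under 5000000 reads and 478 without the fifth 3-month spleen. At that age natural killer genes were 0.92 lower (permutation adjusted p = 0.0490; camera 0.0591 with an estimated correlation) and cholesterol synthesis genes 0.35 lower (0.00892; 0.0767). At 5 and 8 months limma passed 0 genes each, with 423 and 258 at unadjusted p under 0.05 and 0 each in edgeR and DESeq2. The exact permutation passed 0 lists at 5 months and 1 list, lower, at 8 months. No list held in camera with an estimated correlation at either age. Tested directly, 26 against 20 months gave 626 spleen genes (89 higher, 537 lower) and 0 brain genes, where 604 had an unadjusted p under 0.05 and limma was the only tool used. At 26 against 14 months 890 spleen genes passed limma (326 higher, 564 lower), 1484 edgeR (948 higher, 536 lower) and 1752 DESeq2 (987 higher, 765 lower), so the main direction depended on the tool. The limma count ran from 187 (without replicate 5 of 26 months) to 2426 (without replicate 3). The test of any age difference passed 2374, and 1812 to 3996 with 1 of these libraries left out.

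Brain and spleen of the same animals shared 2 genes among those higher at 26 months. They were Fcgr2b, an inhibitory antibody receptor, and Pls1, an actin bundler, named once the overlap was known. They came out of 80 brain and 22 spleen genes tested in both tissues (0.129 expected, 2-sided Fisher p = 0.00724). No gene was lower in both (0.0193 expected, exact Fisher p = 1). At 20 months 6 were higher in both, among them Vwf, Acer2, Podxl and Abca8a (1.29 expected, 2-sided Fisher p = 0.00129), and 0 were lower in both (0.0843 expected). Genes are not independent replicates, so these p-values describe the lists and not the animals. The 26-month overlap is small: it became 0 without brain replicate 1 or spleen replicate 2 of that age, and 10 without spleen replicate 3.

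Mtor itself was lower in every mTOR spleen than in every WT spleen. The normalized counts were 326, 339 and 368 in young WT, 218, 242 and 286 in young mTOR, 346 (21 months), 342 and 330 (23 months) in old WT, and 256 (21 months), 276 and 230 (23 months) in old mTOR. Group values were 344 ± 21.5, 249 ± 34.4, 339 ± 8.56 and 254 ± 23.2 (n = 3 each), a log2 change of -0.45 averaged over age (SE 0.09, limma adjusted p = 0.0118). Within one age Mtor did not pass, with limma adjusted p = 0.0832 in young and 0.133 in old animals. Mtor lies on chromosome 4 from 148448611 to 148557683, plus strand (GENCODE M21 on GRCm38, 1-based). Deptor, an inhibitor that binds the mTOR kinase and a gene outside the naming rule, was 0.68 higher (limma adjusted p = 0.0210). The list of mTOR pathway components as a whole did not pass (camera adjusted p = 0.503).

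Averaged over age, mTOR spleens had less of the genes of helper and effector T cells than WT spleens, and more of genes such as Cd209b and Emcn. In this paragraph 4 values give young WT, young mTOR, old WT and old mTOR, n = 3 each. Il21, the cytokine that follicular helper T cells give to B cells, stood at 57.5 ± 28.5, 2.13 ± 2.82, 66.6 ± 1.58 and 5.66 ± 3.23 (log2 -4.01, SE 0.44, limma adjusted p = 0.000244). Gzmk, a granzyme of effector T cells, stood at 51.0 ± 12.5, 3.79 ± 2.67, 64.5 ± 41.9 and 6.20 ± 4.07 (log2 -3.38, SE 0.41). The immunoglobulin constant region Ighg2c, close in sequence to Ighg2b, stood at 9299 ± 584, 321 ± 315, 8046 ± 5667 and 1096 ± 654 (-3.94, SE 0.52, limma adjusted p = 0.000809). Sostdc1, a secreted antagonist of BMP and Wnt signals, stood at 104 ± 9.18, 18.5 ± 1.41, 122 ± 32.2 and 14.99 ± 7.90 (-2.74, SE 0.24, limma adjusted p = 7.14e-05). The ciliary gene Cfap74 stood at 81.1 ± 44.9, 14.5 ± 2.01, 115 ± 46.7 and 10.6 ± 2.29 (-2.72). The kinase subunit Camk2b stood at 19868.5 ± 2587, 10081 ± 1652, 29111 ± 9870 and 3470 ± 5372 (-2.86, SE 0.66, limma adjusted p = 0.0198). Its old mTOR values were 226, 9671 and 513, and it did not pass edgeR, DESeq2 or limma with the log2 share of Malat1 as a covariate. Higher in mTOR were Cd209b, a lectin of marginal zone macrophages, at 178 ± 81.8, 954 ± 137, 144 ± 65.3 and 881 ± 104 (log2 2.63, SE 0.26, limma adjusted p = 0.000137). The endothelial sialomucin Emcn stood at 37.6 ± 14.5, 177 ± 31.6, 60.1 ± 25.6 and 389 ± 189 (2.45, SE 0.31), and the fatty acid carrier Fabp4 at 289 ± 110, 1372 ± 50.5, 333 ± 103 and 1755 ± 806 (2.31, SE 0.26). The amino acid transporter Slc6a19 stood at 16.5 ± 2.61, 63.6 ± 21.1, 4.22 ± 5.67 and 42.1 ± 14.8 (2.75), and the C-type lectin Clec4b2, a near copy of Clec4b1, at 6.21 ± 4.42, 67.9 ± 6.55, 15.1 ± 5.42 and 64.1 ± 22.6 (2.78). The zinc finger gene Zfp990 changed most, at 1.83 ± 0.63, 470 ± 25.7, 3.21 ± 1.12 and 374 ± 44.7 (6.96, SE 0.19, limma adjusted p = 2.16e-10); it belongs to a family of near-identical copies on chromosome 4, from 145510759 to 145539188, plus strand (GENCODE M21 on GRCm38, 1-based). Of 15512 tested genes 1230 passed limma (497 higher, 733 lower), 1283 edgeR, 1897 DESeq2 and 1189 all 3, and none of the 12 named genes lost its call when any 1 of the 12 libraries was left out. The count fell to 753 without young mTOR replicate 1, 728 without young mTOR replicate 2 and 785 without old WT replicate 1, and was 694 with the Malat1 covariate.

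**Figure D3:**
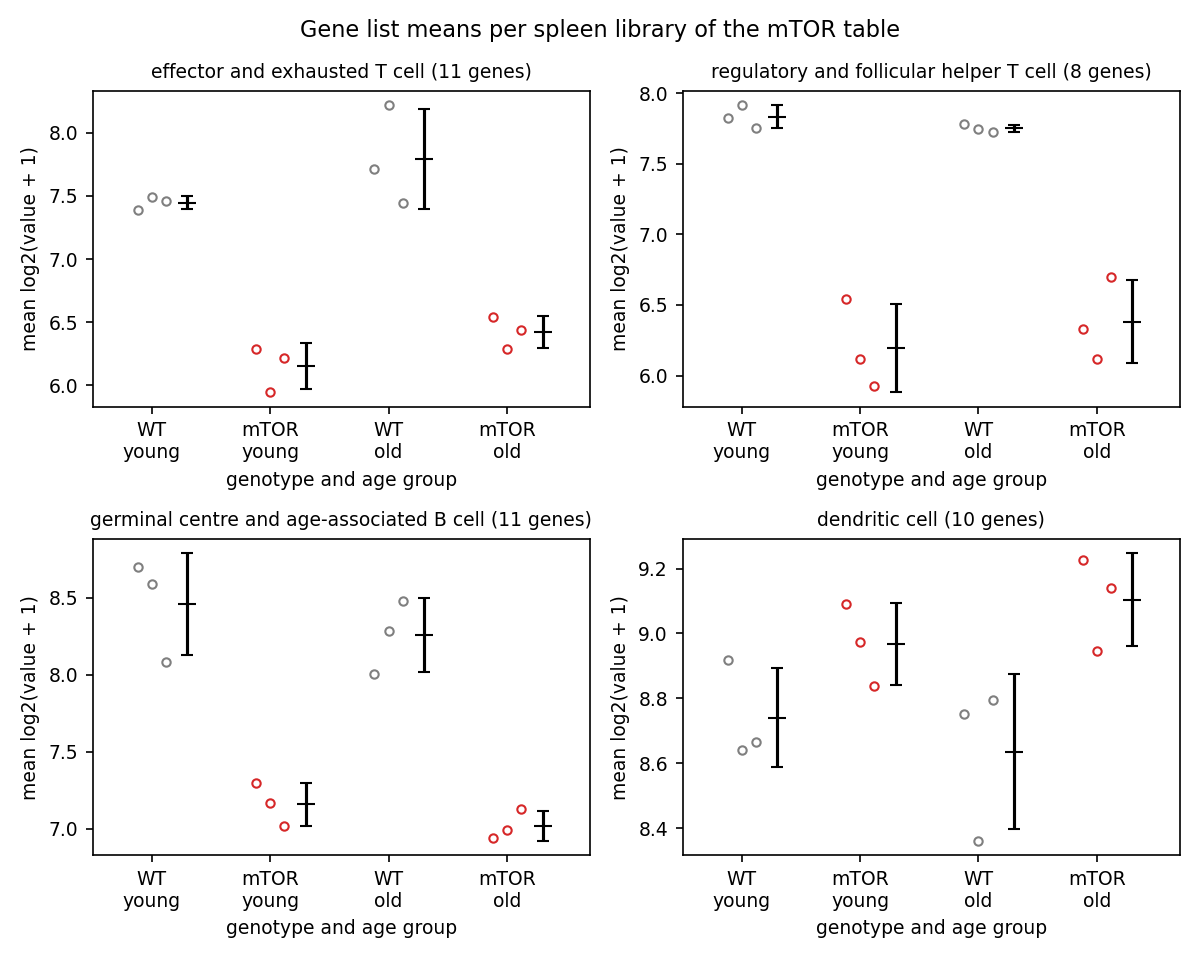
Mean log2 expression of the effector and exhausted T-cell, regulatory and follicular helper T-cell, germinal centre and dendritic cell lists in the 12 spleens of the mTOR table. Points are libraries and bars show mean ± SD.

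Of 34 lists, 20 passed camera at the preset correlation in mTOR against WT averaged over age (3 higher, 17 lower). The 3 that held with an estimated correlation were regulatory and follicular helper T cell, germinal centre and age-associated B cell, and effector and exhausted T cell (adjusted p = 0.0174 for each). In the first, 7 of 8 members passed over all genes. The costimulator Icos stood at 562 ± 147 in young WT, 209 ± 13.8 in young mTOR, 366 ± 44.3 in old WT and 186 ± 14.6 in old mTOR (n = 3 each), and Tnfrsf4, which encodes OX40, changed by -1.54. In the germinal centre list Mybl1, a transcription factor of dividing germinal centre B cells, stood at 319 ± 139, 45.03 ± 7.17, 235 ± 86.2 and 54.0 ± 7.09 (log2 -2.37), with Zbtb32 at -1.45 and the migration receptor S1pr2 at -1.34. In the effector list 8 of 11 members passed, among them the inhibitory receptors Tigit (198 ± 57.6, 44.9 ± 14.4, 292 ± 16.1 and 72.0 ± 31.3; -2.12) and Lag3 (256 ± 39.9, 115 ± 25.5, 377 ± 50.5 and 123 ± 16.7; -1.39). Lists lower only at the preset value included plasma cell and immunoglobulin genes (12 of 15 called; adjusted p = 0.0795 with an estimated correlation), with the antibody-joining Jchain at -1.34 and Sec11c at -0.88. Also at 0.0795 with an estimated correlation were MHC class I (Nlrc5 -0.84, Psmb9 -0.68, Tap1 -0.55), ATF4 targets (the cystine transporter Slc7a11 -1.47), natural killer (Klra8 -2.42), p53 targets (Cdkn2a -1.43, Ccng1 -0.46), interferon-stimulated (Zbp1 -0.90) and inflammatory cytokine genes (Ccl8 -3.90, Ccl4 -2.29, Cxcl9 -1.65). Endoplasmic reticulum stress genes, 10 of 13 called and led by the chaperone Hspa5 (-0.91) and Creld2 (-1.45), stood at 0.0932.

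Further lists lower at the preset value only were cholesterol synthesis (0.402 with an estimated correlation), T cell (0.426), megakaryocyte and neutrophil (each 0.494), cell cycle (0.597) and respiratory chain (0.640). Higher at the preset value only were naive T-cell genes (0.494 with an estimated correlation; Dapl1 1.81, Lef1 0.91, Igfbp4 0.47), extracellular matrix (0.6254; Fbln1 0.92, Col5a1 0.82) and erythroid genes (0.640). In the exact permutation of animals within age, added later, 14 lists passed: 12 lower and 2 higher, naive T cell (adjusted p = 0.0425) and dendritic cell (0.0309), and 10 of them at the smallest possible p of 0.005. Dendritic cell genes did not pass camera in limma (adjusted p = 0.0591). Their receptor Clec9a, which binds dead cells, stood at 882 ± 79.5 (n = 3) in young WT and 1119 ± 240 (n = 3) in young mTOR, and at 862 ± 121 and 1532 ± 28.6 in the old groups. Not past camera were also circadian clock (0.0749), splenic stroma (0.103), adipocyte (0.235), cytosolic heat shock (0.246), MHC class II (0.330), lysosome and glycolysis (each 0.387), B cell, ribosomal proteins and exocrine pancreas (each 0.503), red pulp macrophage (0.555) and immediate early genes (0.647).

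Genotype differences in young and in old animals shared many genes, and no gene passed the test of genotype by age. In young animals 284 genes passed limma (72 higher, 212 lower), 286 edgeR and 908 DESeq2; in old animals 281 (126 higher, 155 lower), 285 and 802. With 1 of the 12 libraries left out limma gave 95 to 423 in young and 62 to 363 in old animals. In old animals of 23 months only it gave 121 with the balance turned (86 higher, 35 lower). In all old animals it gave 49 in a fit of the 2 groups alone and 30 with log2 reads as a covariate, and in young animals 105 with the Malat1 covariate. Shared between the ages were 28 higher genes, among them Cd209b, Emcn and Fabp4 (0.585 expected, 2-sided Fisher p = 6.82e-41), and 76 lower, among them Gzmk, Icos and Hspa5 (2.12 expected, 2-sided Fisher p = 7.14e-104). Both lists came from 1 fit with a shared spread for each gene, so the independence that the Fisher test assumes does not hold. Some shared genes, such as Zfp990, Zfp534 and Draxin, lie within 5 Mb of Mtor. Young and old log2 changes correlated over 15512 genes with Pearson r = 0.522 (Spearman 0.421), though genes are not independent replicates. The effector, germinal centre and helper T-cell lists held with an estimated correlation in young (camera adjusted p = 0.0282, 0.0328 and 0.0282) and in old animals (0.0131, 0.0190 and 0.0190). For the interaction limma, edgeR and DESeq2 passed 0 genes each, with 850 at unadjusted p under 0.05, and the 7 lists past camera at the preset value all had adjusted p = 0.713 with an estimated correlation.

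Calls between genotypes were dense around Mtor on chromosome 4. Within 5 Mb of the gene 27 of 80 tested genes passed averaged over age, Mtor among them, 33.8% against 7.81% elsewhere (odds ratio 6.02, 2-sided Fisher p = 3.75e-11). They went both ways, 14 higher and 13 lower. Named after their values were seen, these include the complement protease Masp2 by 2.51, the neuropeptide Cort by 2.93, Zfp534 by 3.36 and the chloride transporter Clcn6 by 0.86. Lower were the axon guidance factor Draxin by -2.30, Fbxo44 by -1.84, the CD30 receptor Tnfrsf8 by -1.62, Agtrap by -1.35 and the mitochondrial fusion gene Mfn2 by -0.69. In young animals 18 of the 80 passed (odds ratio 16.5) and in old animals 14 (odds ratio 12.004). Counted in stretches of 10 Mb, the one from 140 Mb on chromosome 4 had the highest share of 237, 32 of 93 genes. Among genes named earlier, Zfp990 also lies within 5 Mb of Mtor, and Cfap74 and Tnfrsf4 lie between 5 and 10 Mb from it. Whether DNA linked to the targeted allele accounts for their differences was not tested.

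**Figure D4:**
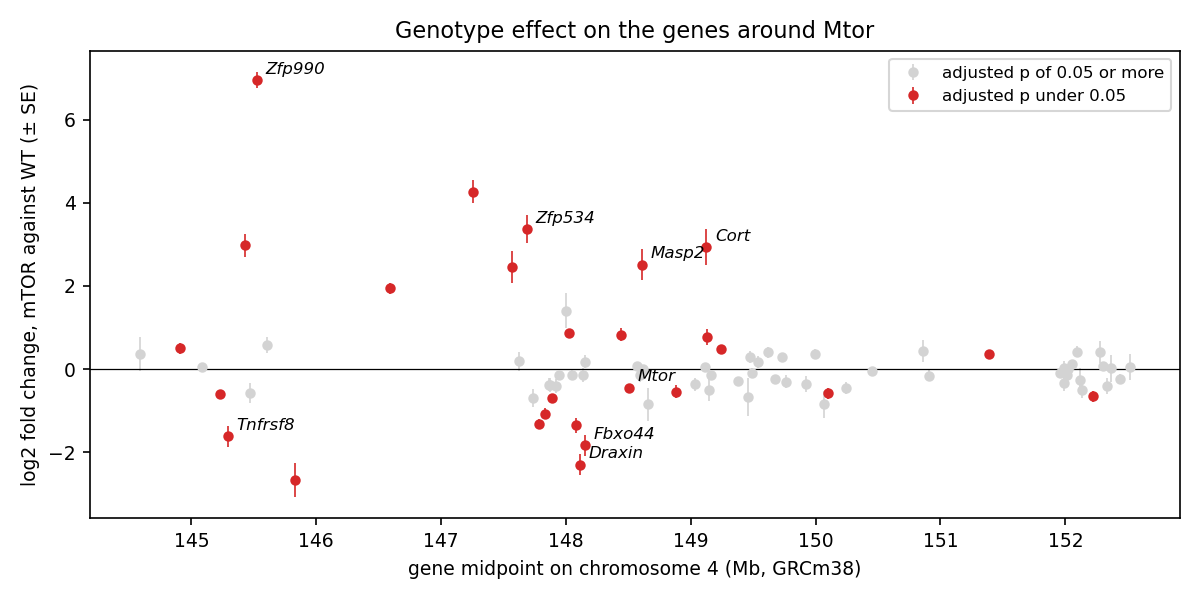
Log2 fold change ± SE of mTOR against WT averaged over age for tested genes within 5 Mb of Mtor on chromosome 4, against gene midpoint.

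Old against young spleens of the mTOR table gave few calls. Averaged over genotype 4 genes passed limma, 1 edgeR and 372 DESeq2; the endocytic adaptor Pacsin1 fell from 429 ± 53.4 in young WT and 453 ± 23.4 in young mTOR to 269.3 ± 9.61 and 265 ± 27.9 in the old groups (n = 3 each; log2 -0.72, SE 0.09, limma adjusted p = 0.0397). It kept its call in 3 of 12 leave-outs. In WT alone 0 genes passed limma (1748 at unadjusted p under 0.05, 0 in edgeR, 102 in DESeq2) and in mTOR alone 1 (0 in edgeR, 124 in DESeq2). With 1 of the 12 libraries left out limma gave 0 to 92 genes averaged over genotype, 0 to 2 in WT and 0 to 42 in mTOR; the 92 and the 42 came without old mTOR replicate 2. Of the lists 11 passed at the preset value and 0 with an estimated correlation: exocrine pancreas (-4.83; 0.4656 with the estimate), naive T cell (-0.56; 0.4656), B cell (-0.36; 0.4656), natural killer (-0.55; 0.4656), effector T cell (0.31; 0.4656), plasma cell (0.55; 0.575), p53 targets (0.34; 0.575), T cell (-0.26; 0.631), ATF4 targets (0.34; 0.668), ribosomal proteins (-0.22; 0.709) and extracellular matrix (0.21; 0.731). Dapl1 stood at 146 ± 66.5 in young WT and 20.9 ± 10.4 in old WT (n = 3 each), and at 226 ± 40.0 and 160 ± 69.7 in young and old mTOR. It was named for the difference between genotypes and not for age. In limma 0 genes passed for age in WT and 0 for the interaction, so these values do not show that its change with age differed between genotypes. Digestive enzymes of the pancreas list averaged 5.59 ± 3.22, 7.26 ± 4.92, 1.96 ± 0.62 and 1.23 ± 0.14 (log2) in young WT, young mTOR, old WT and old mTOR, with a wide spread among the young animals.

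The genes that differed at 26 months in the ageing spleens were followed in the separate mTOR animals. The 32 tested genes of the higher list, Pkhd1l1 and Wipf3 among them, had a median log2 change with age of 0.30 in WT (25 above 0; camera adjusted p = 0.207 with an estimated correlation) and 0.76 in mTOR (30 above 0; 0.0826 with the estimate). The 27 genes of the lower list, with Cr2 and Vpreb3, had medians of -0.29 in WT (0.102 with the estimate) and -0.25 in mTOR (0.0912). Between genotypes the signs were opposite to ageing: averaged over age the higher list had a median of -0.32 (11 above 0; preset adjusted p = 0.000769, and 0.216 with an estimated correlation) and the lower list 0.17 (20 above 0; 0.216 with the estimate). The signs depended on the genes chosen. With age in WT the higher list had a median of -0.122 when drawn by edgeR, -0.102 by DESeq2, -0.0563 with array weights, -0.0633 without libraries under 5000000 reads and -0.0489 or -0.115 without spleen replicate 3 or 4 of 26 months. Taken from 20 against 3 months, it had a median of 0.111 between genotypes averaged over age and 0.248 in old animals. The interaction did not pass for either list in the main analysis (limma camera adjusted p = 0.218 and 0.890), and for the higher list this depended on the choice: at the preset correlation it passed, with a positive median, when the genes were drawn by edgeR, by DESeq2, with array weights, from 20 against 3 months or as the 200 of smallest p, with the pancreas covariate, without libraries under 5000000 reads and without the fifth 3-month spleen. For the lists of 20 against 3 months and of the 200 smallest p the adjusted p was 0.379 and 0.640 with an estimated correlation. The interaction of the higher list also passed at the preset correlation in 6 of 15 leave-outs of 1 library. Among these, the fit without spleen replicate 1 of 26 months had a negative median of -0.284. Log2 changes with age in the ageing spleens and in WT of the mTOR table correlated with r = 0.153 over 15106 genes. Of 59 called genes 49 had the same sign, against 296 of 691 in edgeR and 410 of 870 in DESeq2. With mTOR animals in place of WT, r was 0.333 and 53 of 59 had the same sign by limma. Genes are not independent replicates.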

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

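All predictions and tests in this part were chosen after results were seen.

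8 of 48 gene-group pairs tested had 1 sample far from the others, where chance flags about 1 in 20 groups (2.4 expected). In brain at 3 months C4b was 102.46 in replicate 1 against 55.98 to 74.13 in the others, and A2m 31.55 in replicate 4 against 12.17 to 19.10. In brain at 26 months replicate 1 stood apart in Serpina3n (446.5 against 104.2 to 192.6), Ier2 (83.22 against 36.04 to 48.16) and Arl4d (132.8 against 68.58 to 82.78). In spleen at 3 months replicate 5 stood apart in Pkhd1l1 (33.14 against 11.88 to 19.67), Cr2 (3273.8 against 10088 to 12977) and Rapgef4 (119.3 against 252.8 to 347.5).

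7 lists differed between the age effect in mTOR and the age effect in WT by the camera test of the interaction at the preset correlation. Each had adjusted p = 0.713 with an estimated correlation. They were plasma cell and immunoglobulin (adjusted p = 0.00982, median difference 0.55), erythroid (0.00982; 1.63), cell cycle (1.06e-08; 1.02), red pulp macrophage (0.0192; 0.35), megakaryocyte (0.0192; -0.51), exocrine pancreas (0.0192; -2.59) and adipocyte (0.0192; 1.56). Random divisions gave as many such lists in 85 of 100 cases. They exchanged genotype within each age, so the difference between genotypes can enter them as an interaction. They therefore cannot show whether these 7 lists are more than chance gives.

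Replicates 1 and 6 of brain at 5 months, and replicates 4 and 7 at 8 months, were closer than separate draws of reads from 1 RNA sample could be, with variance ratios of 0.496 and 0.614 where separate draws give 1. In the 5-month pair 0 of 16271 genes had more reads in the shallower library (487 expected), and in the 8-month pair 864 of 16524 (1205 expected), which fits reads held in common by both files. The explanation that 1 animal was entered under 2 numbers did not hold, since the spleens of the same animal numbers had ratios of 5.76 and 4.85. Nor was the deeper 5-month library the shallower one sequenced further, since its remaining reads gave 2.15 against the shallower and a median of 2.004 against the 43 other brain libraries; the same subtraction gave 3.63 in the 8-month pair, where the shallower library has genes with more reads too. No biological explanation was tested, and counting the pairs as 1 sample each changed no gene count by more than 1.5-fold.

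Called genes between genotypes were dense within 5 Mb of Mtor, with odds ratios of 16.5 in young and 12.004 in old animals. DNA from another strain carried along with the targeted allele could account for a cluster that repeats at both ages and goes both ways. All titles of the mTOR table carry BL6J, and the labels do not give the strain of the stem cells. An effect of lower Mtor on genes wherever they lie would give an odds ratio near 1 only if such genes were evenly spread. They may not be, as 36 of 165 genes were called on chromosome 12 from 110 Mb, averaged over age. That stretch holds immunoglobulin heavy chain genes such as Ighg2c and Ighg3, and may not speak for genes of other kinds. The odds ratio alone therefore cannot set this effect aside. Reads shared within the zinc finger cluster do not suffice, since 17 called genes other than Mtor were neither zinc finger nor unnamed genes. Averaged over age the density went on between 5 and 10 Mb, with 17 of 110 genes called against 7.75% farther away (2-sided Fisher p = 0.00630). Within 1 age this did not pass, with 4 of 110 called in young and 4 of 110 in old animals (2-sided Fisher p = 0.123 and 0.124). Effects of linked variants on genes elsewhere were not tested, so the cause of the 1201 calls outside 5 Mb was left open.

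The spleen had 1733 calls at 20 months and 60 at 26 months. Uneven depth of the other libraries does not account for this, since the ratio of the counts was 28.6 without the shallow libraries of 3, 5 and 20 months and 34.0 with log2 reads as a covariate. A single library, replicate 3 of 26 months, could account for the low count, since the fit without it gave 1929 and 1789 calls, a ratio of 1.08. It was picked as the 26-month library whose loss gave the most 26-month calls, so a low ratio was favoured by the choice. Other single libraries moved the count too. Without replicate 4 the calls were 1734 and 682, and the 26-month count also rose without the fifth 3-month spleen. Without replicates 1, 2 and 5 of 26 months it fell to 16, 0 and 3. The low depth of replicate 3 cannot be told apart from its other properties, as it is the only 26-month library under 5000000 reads and the ratio without all such libraries was 0.463. A lower share of lymphocytes alone would move all other cell types alike, yet the neutrophil list rose by 2.80 (log2) more than the red pulp macrophage list, a gap above its spread of 0.756. Between 26 and 20 months tested directly, 626 genes passed limma.

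Dividing the same samples at random asked how often a count as large arises without the labels. In brain, 1 of 100 divisions, the real one, reached the 27 genes of 20 months (highest other 5), the 103 of 26 months (10), the 26 of 26 against 14 months (1) and the 75 of any age (1), and 4 of 100 the 14 lists of 26 months (16). With 0 genes at 5, 8 and 14 months all 100 were as large (highest other 1, 0 and 84). In spleen 1 of 100 reached the 52 genes of 14 months (highest other 3), the 1733 of 20 months (1368) and the 2374 of any age (188), 2 the 60 genes (377) and the 21 lists (21) of 26 months, and 4 the 890 of 26 against 14 months (1979), while 100 matched the 0 at 5 and 8 months (6 and 23). Among the mTOR and WT spleens 1 of 100 reached the 1230 genes between genotypes averaged over age (highest other 12), and 5 the 20 lists (26), so that such a number of lists is not excluded without the labels. For age averaged over genotype 4 of 100 reached the 4 genes (171) and 42 the 11 lists (17), and for the interaction 100 reached 0 genes (6) and 85 the 7 lists (23). Divisions for the interaction exchanged genotype within each age, so a difference between genotypes can enter them as an interaction. Comparisons of 3 against 3 animals allow 10 divisions, too few for a share under 0.05. There the real and highest other counts were 284 and 2 genes and 14 and 19 lists in young animals (1 and 3 divisions as large), 281 and 0 genes and 21 and 18 lists in old animals (1 and 1), 0 and 1 genes and 7 and 18 lists for age in WT (10 and 8), and 1 and 205 genes and 15 and 14 lists for age in mTOR (2 and 1).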

How the results depend on the processing

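Each result was computed again under other choices, of which the alternatives on offset, filter, normalization, weights, fit, tools, leave-outs, age pooling, correlation and signature were written before the data were examined. Chosen after results were seen were the covariates and the pairing of animals. So were the removal of shallow libraries, of the fifth 3-month spleen and of the region around Mtor. Separate counting of all brain libraries was the plan, and averaging the brain pairs was decided after the data were examined. Unless a sentence says otherwise the numbers are genes called by limma, and the cause of a changed count was not tested. The replicate numbers used here follow only the order of the accessions.

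The C4b rise at 26 months held under every choice. Of the 12 named genes of mTOR against WT averaged over age, Camk2b alone lost its call. It did so by edgeR, by DESeq2 and with Malat1 as a covariate. The spleen count at 26 months ran from 0 to 1789 when 1 library of that age was left out. With an offset of 5 in place of 1, old against young gave 1 gene in WT and 2 averaged over genotype. Quantile normalization left 287 list results and 235 named-gene results on the same side of the threshold, brought 15 and 1 past it and 4 and 2 out, and moved no count by more than 1.5-fold. Without the filter on low values the counts were 20 for spleen at 14 months, 25 for spleen at 26 months, 181 for mTOR against WT in old animals, 0 for age in mTOR, 1 for age averaged over genotype and 1 gene higher in both tissues. In that setting the median of the ageing signature in mTOR against WT was -0.0880 (higher list, young), 0.106 (lower list, young), 0.177 (lower list, old) and 0.124 (lower list, averaged), each without a pass.

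Array weights, which give noisy libraries less say, raised most counts. Brain went to 76 at 20 months, 163 at 26 months, 64 at 26 against 14 months and 167 for any age. Spleen went to 2370 at 14 months, 5228 at 20, 1675 at 26, 1999 at 26 against 14 months and 6504 for any age. mTOR against WT in old animals went to 423, age averaged over genotype to 10, and genes higher in both tissues to 19. The larger signature drawn from those calls had medians of 0.0579 for its higher list in old mTOR against WT and -0.0563 with age in WT, both of the other sign, and 0.301 and -0.0753 for the interaction of the higher and lower lists, which both passed, the lower with the other sign.

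Fitting only the 2 groups compared lowered counts: brain 53 at 26 months and 14 at 26 against 14 months; spleen 875 at 20 months, 0 at 26 and 255 at 26 against 14 months; mTOR against WT in old animals 49; age in mTOR 0; genes higher in both tissues 0. Spleen at 14 months rose to 119. edgeR on the recovered reads called 41 brain genes at 20 months, 707 spleen genes at 26 months, 1484 at 26 against 14 months, 0 for age in mTOR, 1 for age averaged over genotype and 7 higher in both tissues. DESeq2 called in brain 3 at 14 months, 82 at 20, 169 at 26, 58 at 26 against 14 months and 174 for any age. In spleen DESeq2 called 231 at 14 months, 896 at 26, 1752 at 26 against 14 months and 4120 for any age, and 12 genes higher in both tissues. In the mTOR table DESeq2 called 908 genes between genotypes in young and 802 in old animals, 1897 averaged over age, 102 for age in WT, 124 in mTOR and 372 averaged over genotype. In simulated data drawn from the mTOR table DESeq2 had a larger share of false calls than limma. Signatures drawn by edgeR and DESeq2 had higher-list medians of 0.204 and 0.184 in old mTOR against WT and -0.122 and -0.102 with age in WT, all of the other sign. Averaged over age they were -0.0420 and -0.0607, and for the interaction, which passed in both, 0.469 and 0.427. The correlation of the age effect between the 2 spleen tables was 0.0917 and 0.0946.

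Leaving out 1 library of 26 months at a time gave 67 (without replicate 1) to 98 brain genes at 26 months, and 7 (without replicate 1) to 23 at 26 against 14 months, with 17 without replicate 4 or 5. In spleen it gave 0 (without replicate 2) to 1789 (without replicate 3) at 26 months, 187 (without replicate 5) to 2426 (without replicate 3) at 26 against 14 months, and 1812 to 3996 for any age. The count at 26 against 14 months was 234 without replicate 1 and 349 without replicate 2. Genes higher in both tissues ran from 0 to 10 and lower from 0 to 1.

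In the mTOR table, leaving out any 1 of 12 libraries gave 95 (without young mTOR 2) to 423 genes between genotypes in young animals, with 97 without young mTOR 3, 112 without young mTOR 1 and 152 without young WT 1. Old animals gave 62 (without old mTOR 1) to 363, with 79, 109 and 150 without old WT 1, 2 and 3, and 152, 183 and 184 without young mTOR 1, 2 and 3. Averaged over age the range was 728 (without young mTOR 2) to 1306. Age gave 0 to 2 genes in WT (2 without old WT 2), 0 to 42 in mTOR (42 without old mTOR 2, 22 without young mTOR 2) and 0 to 92 averaged (92 without old mTOR 2, 33 without young mTOR 2). The interaction gave 0 to 1 (1 without old mTOR 2), and its lists past camera 3 (without old mTOR 3) to 11 (without young mTOR 2).

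Signature medians over the same leave-outs ran as follows. In old mTOR against WT the higher list went from -0.708 to 0.123 (positive without spleen replicate 4 of 26 months) and the lower from 0.0532 to 0.268. In young animals the lower list went from 0.0835 to 0.305. Averaged over age the higher list went from -0.721 to -0.0578 and the lower from 0.0723 to 0.211. With age in WT the higher list went from -0.115 (without spleen replicate 4) to 1.00 and the lower from -0.385 to -0.119, and in mTOR the lower from -0.329 to -0.182. Averaged over genotype the lower list went from -0.346 to -0.172, and the interaction of the higher list from -0.284 to 0.486, passing in 6 of 15 leave-outs, the -0.284 (without spleen replicate 1) among them. Reversed medians also came without spleen replicate 3, at 0.0333 in old mTOR against WT and -0.0489 with age in WT. The age correlation of the 2 spleen tables went from 0.0330 (without young WT 1) to 0.190.

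With old animals of 23 months only, 121 genes passed between genotypes in old animals and 728 averaged over age. Age gave 7 genes in mTOR and 7 averaged, the interaction 1, and the lower signature list in old mTOR against WT a median of 0.108. With an estimated correlation the lists past camera numbered 6 in brain at 26 months, 0 in spleen at 26 months, 3 between genotypes in young, in old and averaged, and 0 for age in WT, age in mTOR, age averaged and the interaction. The signature lists gave estimated adjusted p of 0.216 (higher and lower, young mTOR against WT), 0.306 and 0.216 (old), 0.216 for both (averaged), 0.207 and 0.102 (age in WT), 0.0826 and 0.0912 (age in mTOR) and 0.0826 for both (age averaged).

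Drawing the signature from 20 against 3 months gave medians of -0.0494 (higher list, young mTOR against WT), 0.248 and -0.0352 (higher and lower, old), 0.111 and 0.0422 (averaged), and 0.263 and -0.152 (interaction, both passing). Of these the old values, the averaged higher value and the lower interaction value had the other sign. The 200 genes of smallest p per direction gave higher-list medians of 0.0293 (old, other sign), 0.0288 (age in WT) and 0.271 (interaction, passing).

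With log2 reads as a covariate the counts were 80 for spleen at 14 months, 30 between genotypes in old animals and 0 for age in mTOR and averaged, with 4 lists past for age in WT. The erythroid list of the interaction then had adjusted p = 0.966 by camera and the other direction. With the log2 share of Malat1 as a covariate spleen gave 1253 at 14 months, 3159 at 20, 111 at 26 and 527 at 26 against 14 months. The mTOR table then gave 105 in young animals, 694 averaged over age, 0 for age in mTOR and 1 for age averaged, and an age correlation between the spleen tables of 0.0207. With the exocrine pancreas mean as a covariate spleen gave 1125 at 20 months and 101 at 26, age gave 1 gene in WT, 0 in mTOR and 1 averaged, and 4 lists passed for age in WT. There the pancreas list itself, which the covariate removes, had adjusted p = 0.915 by camera in the other direction. The interaction of the higher signature list was 0.284 and passed, and the age correlation 0.285.

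Without the libraries under 5000000 reads brain gave 1 gene at 14 months and 10 at 26 against 14 months. Spleen gave 1 at 5 months, 13 at 14, 685 at 20, 1481 at 26 and 2546 at 26 against 14 months, and 4 genes were higher and 1 lower in both tissues. The signature drawn there had higher-list medians of 0.0308 in old mTOR against WT and -0.0633 with age in WT, of the other sign, and 0.259 for the interaction, which passed. Without the shallow spleens of 3, 5 and 20 months alone the counts were 486 at 20 months and 17 at 26. Without the fifth 3-month spleen the counts were 478 at 14 months, 2739 at 20, 685 at 26 and 5 genes higher in both tissues. The signature then had medians of 0.0558 (higher, other sign) and 0.0359 (lower) in old mTOR against WT and 0.235 for the interaction of the higher list, which passed. In the mTOR table each mTOR animal has a WT animal of the same age with a neighbouring animal number, and the labels do not say that these are related. Over 15512 genes the deviations of such animals from their group means correlated by -0.233 to 0.0649, over 0.1 in 0 of 6 pairs. Of the 6 mTOR animals 2 correlated best with the WT animal of neighbouring number. With 3 animals per group these correlations cannot show whether such animals are related or were handled together. With these pairs as a replicate block 183 genes passed between genotypes in old animals and 0 for the interaction, and the counts in young animals and averaged over age moved by less than 1.5-fold. The block brought 4 list results and 2 named-gene results past the threshold and 4 named-gene results out. Counting the members of the brain pairs separately changed no count by more than 1.5-fold. Nor did leaving out the 80 genes within 5 Mb of Mtor. That step could not move the genotype counts so far, as those genes held 27 of 1230 calls averaged over age.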

Other observations

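Erythroid, cell cycle and megakaryocyte genes of the spleen had a larger SD between animals at 20 and 26 months than at 3 months. Erythroid genes, from haemoglobin to membrane proteins of red cells, had a list mean of 7.29 ± 0.76 (log2, n = 7) at 3 months and 8.42 ± 1.34 (n = 9) at 5, 8.47 ± 1.05 (n = 8) at 8, 7.93 ± 0.53 (n = 9) at 14, 8.88 ± 2.08 (n = 7) at 20 and 9.53 ± 2.73 (n = 5) at 26. Cell cycle genes had SDs of 0.32 at 3 months, 0.38 at 5, 0.43 at 8, 0.19 at 14, 1.00 at 20 and 1.39 at 26. Megakaryocyte genes had SDs of 0.38, 0.97, 0.49, 0.66, 1.00 and 1.95 at the same ages, so that their spread at 5 months was close to that at 20. For B-cell genes the SD was larger at 26 months only, and for extracellular matrix and adipocyte genes it stayed near or below that of 3 months at both ages. B-cell genes stood at 11.58 ± 0.41 at 3 months, 11.25 ± 0.39 at 14, 10.59 ± 0.40 at 20 and 10.76 ± 0.98 at 26. Extracellular matrix genes stood at 7.30 ± 0.74 at 3 months, 8.06 ± 0.66 at 14, 8.12 ± 0.78 at 20 and 7.69 ± 0.49 at 26, and adipocyte genes at 3.20 ± 0.88, 4.66 ± 1.43, 4.40 ± 0.88 and 3.94 ± 0.99. These spreads were described after they were seen and not tested.

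In brain, the lists of antigen presentation and interferon response had these means over the ages. MHC class I genes stood at 5.23 ± 0.28 (n = 7) at 3 months, 5.39 ± 0.18 (n = 8) at 5, 5.44 ± 0.22 (n = 7) at 8, 5.67 ± 0.10 (n = 9) at 14, 5.81 ± 0.15 (n = 7) at 20 and 6.15 ± 0.30 (n = 5) at 26. MHC class II genes stood at 3.94 ± 0.26, 3.81 ± 0.27, 3.89 ± 0.34, 4.13 ± 0.25, 4.33 ± 0.28 and 4.37 ± 0.25, and did not pass at 26 months (camera in limma, adjusted p = 0.0511). Interferon-stimulated genes stood at 4.57 ± 0.31, 4.49 ± 0.17, 4.47 ± 0.23, 4.75 ± 0.16, 4.96 ± 0.22 and 5.32 ± 0.20.

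Camk2b, a kinase subunit best known from neurons, was abundant and uneven in spleen. Over the 45 ageing spleens it averaged 7435 ± 4491 and ran from 430 to 22234, with an SD within groups of 1.00 (log2) against a median of 0.347 for genes at a mean of 1000 or more, rank 15 of 1331. In the 12 spleens of the mTOR table it ran from 226 to 37279, with an SD within groups of 1.46, rank 14 of 2316. In brain it averaged 4560 ± 506 over 43 samples with an SD within groups of 0.150, rank 1074 of 1767. It was singled out after its values were seen.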
